A study of Mus musculus with 8 samples.

How the data were processed

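RNA from whole mouse liver was measured on 1-colour (Cy3) Agilent arrays, 1 array per sample, in 4 groups of 2: male and female, wild type and liver-specific Bcl6 knockout. Per the labels' protocols, total RNA was extracted with Trizol, checked on a Bioanalyzer and labelled with a one-colour low-input kit. Per the file headers, the deposited intensity values are the processed signals of Agilent Feature Extraction 11.5.1.1, which subtracts the background and corrects a spatial trend on 1 array at a time. The submitters' processing notes name version 9.1.3.1 instead. The files also hold raw median intensities of each spot and of its background, per the file headers. The deposited value table holds log2 values: on every array it equalled the log2 of the processed signal minus 1 constant between 6.99 and 7.30, within 0.01 for 100% of the probes compared, and it was not centred per gene. Whether each array came from a separate animal is not given in the sources used here beyond the replicate names, so the p-values measure only the spread between these samples.

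All 8 arrays lay on 1 slide with 1 scan time. Row 1 of the slide held the females and row 2 the males, so row and sex cannot be told apart in the comparisons between sexes; genotypes were mixed within each row. Each array had 62976 spots, 59305 of them other than controls, with 55 to 139 marked by the scanner's software as uneven or as outliers (left out here) and 0 saturated. Spots of 1 probe were averaged, giving 56605 probes. Probes carry RefSeq accessions, and 32994 of them were named through the reference list of mouse genes (assembly GRCm38.p6) with 22911 symbols; 23611 stayed without a symbol and kept their identifier. The array's own grid is annotated on mm9, so no coordinates are given and the reference list served only for names, chromosomes and neighbour order.

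From the processed signals, log2 values were computed and each array's 75th percentile was subtracted. A probe was kept if the scanner's software called it well above background on both arrays of at least 1 group (33586 probes). For a gene with several kept probes (5628 genes), the probe with the highest mean over all 8 arrays stood for the gene, leaving 26556 genes and unnamed transcripts. Limma 3.58.1 in R 4.3.3 fitted 4 group means to all 8 arrays (lmFit, eBayes, 4 residual degrees of freedom and 2.07 prior ones), and p-values were adjusted by Benjamini-Hochberg over the 26556 at a threshold of 0.05. There were 5 contrasts: knockout minus wild type in males and in females, males minus females in wild type and in knockout, and the interaction. The median SE was 0.162 on the log2 scale, and 0.229 for the interaction. Where a gene was well above background on no array of the lower group, the fold is a lower bound written "at least": each value of the lower group below the lowest signal well above background on its array was raised to that signal before the difference was taken. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

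The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, per contrast, the 8 genes with the largest rise and the 8 with the largest fall (5 and 5 for the interaction) among those past the threshold whose arrays did not overlap between the groups, read well above background on both arrays of the higher group and saturated on none, with a gene symbol; Bcl6; Xist, Ddx3y, Kdm5d, Uty and Eif2s3y; and up to 4 members of each list with the smallest adjusted p. Non-overlap was not asked for the interaction. Some genes that changed are not reported here. There were 28 lists: male-biased and female-biased liver genes, growth hormone and STAT5 signalling, PPARA targets and fatty acid oxidation, lipogenesis and triglyceride synthesis, cholesterol synthesis and uptake, bile acid synthesis and transport, CAR and PXR targets and drug metabolism, gluconeogenesis and glucose handling, acute phase and inflammation, interferon response, genes repressed by Bcl6 in lymphocytes, circadian clock, cell cycle, endoplasmic reticulum stress, extracellular matrix and fibrosis, Y-linked genes and Xist, and markers of hepatocytes, macrophages and Kupffer cells, T and NK cells, B and plasma cells, neutrophils, endothelial cells, stellate cells, cholangiocytes, erythroid cells, pancreatic acinar cells and adipocytes. Of the 39 female-biased genes 8 were also in another list. These were Cux2 and Prlr (growth hormone), Acot3, Cd36, Cyp4a10 and Cyp4a14 (PPARA targets), Cyp2b10 (CAR and PXR) and Abcc4 (bile acids). Of the 27 male-biased genes 1 was, Cyp7b1 (bile acids). The changes of these genes count in both lists. Each list was tested in each contrast with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of that contrast, and again with an estimated correlation. Of 140 list tests 39 passed with the preset value and 2 with an estimated one: the female-biased list in the wild-type sex comparison and in the interaction. Counts given as adjusted over the list alone re-adjusted the members' limma p-values within the list and take changes in either direction. Camera compares a list with the other genes. Fry, also run, does not: its p-value tests whether a list's genes move, on balance, 1 way, and its mixed p-value whether they change in either direction. In males labelled knockout its adjusted p was 0.00204 for the male-biased and 0.000486 for the female-biased list.

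Calls shared between comparisons were set against independent lists of the same sizes (the product of both counts over the number tested) and, where the comparisons shared wild-type arrays, against 100 simulated sets of unchanged knockout arrays. The steps were tested on simulated data with 26498 genes, of which 200 were changed per draw in 10 draws. In the simulated male knockout comparison, 0.6% of genes changed 1.5-fold, 32% of those changed 2-fold, 79.2% of those changed 4-fold and 88.2% of those changed 8-fold were called, none with the wrong sign, and 4.12% of calls were false. A list of 25 genes shifted by 0.5 (log2) was called in 10 of 10 draws in the simulated female comparison, and 1 of 270 unshifted lists was called. The simulated genes varied independently of each other. The list result therefore says nothing about false list calls where the genes of a list vary together. The alternatives were normexp background correction (offset 50) on the median spot and background intensities, quantile normalization, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, the deposited value table, a mean-variance trend with a robust prior, a fit of only the 2 groups compared, the replicate number or the slide column as a block, other thresholds, and leaving out each array in turn. The mean spot intensity that the normexp alternative was first planned on is not among the columns of the files used here. Groups of 2 are too small for a test of outlying arrays or of other splits of the samples.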

Results

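Transcript levels were measured in the livers of male and female mice labelled wild type or knockout for Bcl6, a zinc-finger repressor of transcription best known from B and follicular helper T cells. Per the labels, the animals were 10 to 11 weeks old, the knockout was specific to the liver, and whole liver was taken. There were 4 groups (male wild type, male knockout, female wild type, female knockout) with n = 2 arrays each, 8 arrays in all. Each array carried 59305 spots other than controls. Between 33677 and 36459 of them were well above background on an array, and the 75th percentile of the signal lay between 182 and 221. The number of arrays limits the precision. After filtering, 26556 genes and unnamed transcripts were tested, 15522 of them with a gene symbol. On the first principal component, with 52.3% of the variance, the 4 arrays labelled knockout lay between -53.6 and -50.9 and the 4 wild-type arrays between 28.9 and 73.6. On the second, with 19.9%, wild-type males (30.0 and 40.7) lay far from wild-type females (-59.9 and -40.7), while the arrays labelled knockout lay between -6.83 and 22.8. Across genes, which are not independent replicates, male and female arrays labelled knockout correlated at 0.988 to 0.991, and male and female wild-type arrays at 0.973 to 0.981. Replicates of a group correlated at 0.987 to 0.993.

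Bcl6 itself was read by 1 probe, and it was not lower in the arrays labelled knockout. On the log2 scale relative to each array's 75th percentile, it was 3.44 ± 0.75 (mean ± SD, n = 2) in wild-type males and 4.25 ± 0.34 in males labelled knockout. In females it was 1.91 ± 1.48 in wild type and 3.01 ± 1.97 in the arrays labelled knockout, with single values of 2.95 and 0.86 against 1.62 and 4.41. The difference was 0.81 ± 1.06 (SE) in males (limma, adjusted p = 0.676) and 1.11 ± 1.06 in females (adjusted p = 0.556), with an SE that pools the spread of all 4 groups. In females the difference was smaller than the SD of either group. In males it was larger than both, and the arrays did not overlap (3.97 and 2.91 in wild type against 4.49 and 4.01); a fit of the male groups alone gave an SE of 0.426. Without female knockout replicate 2 the female difference was -0.29. Where this probe lies relative to the deleted part of the gene is not given in the sources used here, so it checks none of the genotype labels, and each direction given for knockout follows the labels. The sex labels could be checked: Xist, the RNA that silences an X chromosome in females, was at least 22.8-fold lower in male than in female wild-type arrays and at least 24.3-fold lower in males of the arrays labelled knockout. The Y-linked Ddx3y was at least 10.9-fold and at least 10.3-fold higher in males, and Eif2s3y at least 85.9-fold and at least 69.3-fold higher. Over Xist and 4 Y-linked genes, the smallest gap between male and female arrays was 3.92 (log2) in wild type and 4.37 in the arrays labelled knockout.

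**Figure D1:**
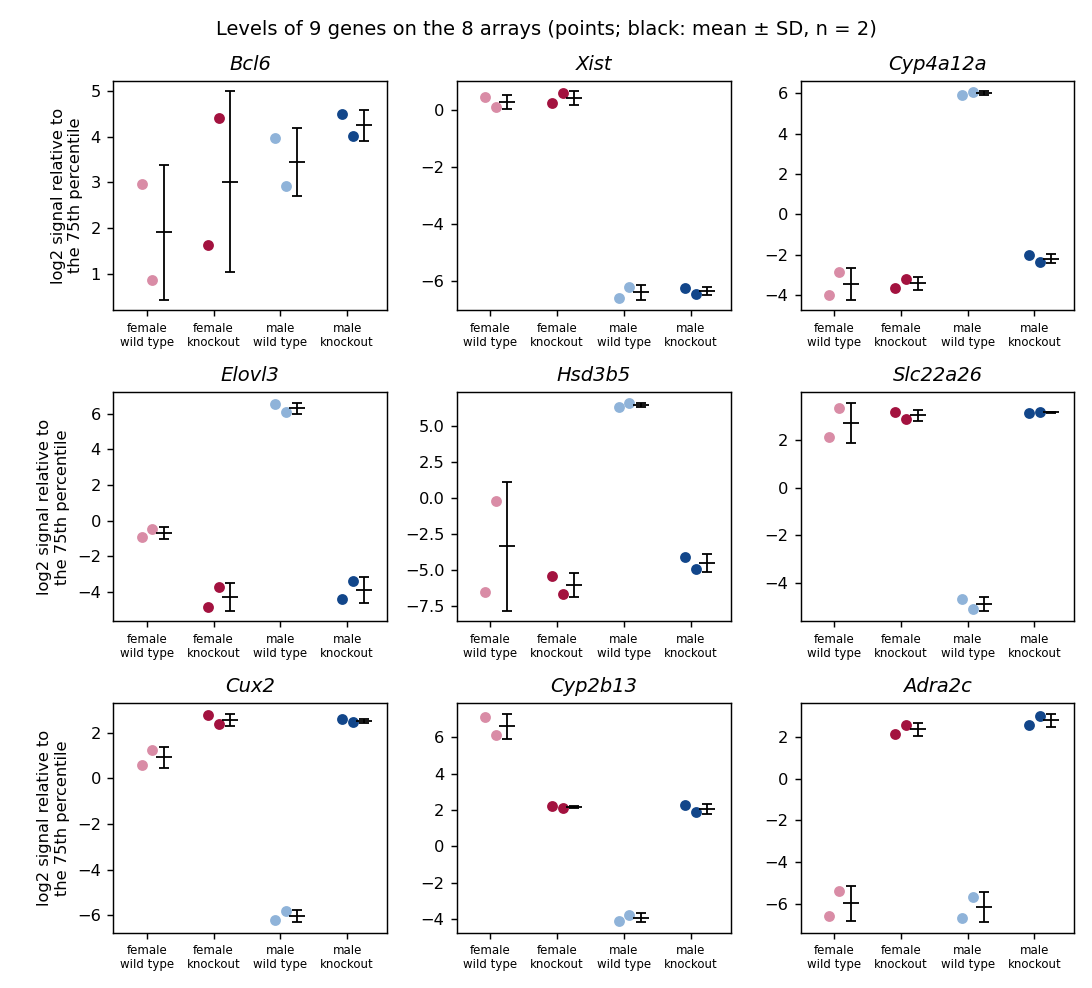
Levels of 9 genes on the 8 arrays, as log2 signal relative to each array's 75th percentile; colored points are arrays and black marks the mean ± SD of a group (n = 2). Cyp4a12a fell by 8.18 in the males labelled knockout and Cux2 rose at least 109-fold, while the mean of Bcl6 was not lower in either sex.

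The first comparison asked which genes differ between the sexes in wild-type liver. Wild-type males had far higher levels of Cyp4a12a, a fatty acid hydroxylase, and of Elovl3, a fatty acid elongase: 691-fold (log2 9.43 ± 0.38 SE, n = 2 per group) and 128-fold (7.00 ± 0.48) above females. They had far lower levels of the cytochrome P450 Cyp2b13, 1473-fold below females. Cux2, a transcription factor expressed in female liver, was at least 35.7-fold lower in males. By limma with Benjamini-Hochberg adjustment, 256 of 26556 passed the threshold, 160 higher and 96 lower in males, and 205 of them differed by at least 2-fold. Other large male excesses were in Cyp4a12b (1139-fold, adjusted p = 0.00306), Nat8f5 (113-fold) and Nat8 (37.2-fold), both related to N-acetyltransferases. On the female side stood the sulfotransferases Sult2a2 (at least 1012-fold lower in males, adjusted p = 0.00743) and Sult3a1 (at least 69.7-fold), the organic anion transporter Slc22a26 (at least 124-fold) and the peroxisomal oxidase Hao2 (at least 32.4-fold). Several of these sizes depended on the wild-type females. Without replicate 1 and without replicate 2 of these, Cyp4a12b was 536-fold and 2420.4-fold higher in males, and the lower bounds were 313-fold and 3268-fold for Sult2a2, 151-fold and 32.3-fold for Sult3a1, 187-fold and 81.9-fold for Slc22a26 and 16.8-fold and 62.6-fold for Hao2. Sequences of the Cyp4a12, Cyp2b, Cyp2c, Cyp3a, Sult2a and Mup families are close enough for a probe to bind several members, so single members of these families are uncertain.

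Of the list of male-biased liver genes fixed before the data were examined, 9 of 24 measured members were higher in males and none lower (20 adjusted over the list alone, median log2 2.55), including the steroid hydroxylases Cyp7b1 (3.70 ± 0.14) and Cyp2d9 (2.94 ± 0.14) and complement C6 (3.77 ± 0.22). Camera gave the list adjusted p = 2.77e-18, and adjusted p = 0.162 with an estimated correlation. Of the female-biased liver genes, 16 of 37 were lower in males (31 adjusted over the list alone, median -2.05, camera adjusted p = 3.25e-33), and this call held at adjusted p = 0.0477 with an estimated correlation. The median was also -2.05 with members not well above background set to their bound. Among PPARA targets and fatty acid oxidation genes, 3 of 43 were lower in males (13 adjusted over the list alone), among them the acyl-CoA thioesterases Acot3 (-4.38) and Acot4 (-1.58). Its camera adjusted p = 6.04e-06 became adjusted p = 0.561 with an estimated correlation. CAR and PXR targets and drug metabolism genes had 2 of 30 lower in males, Cyp2b10 at -4.93 (5 adjusted over the list alone, camera adjusted p = 6.50e-05, adjusted p = 0.373 with an estimated correlation). Extracellular matrix and fibrosis genes had 2 of 20 lower (6 adjusted over the list alone, camera adjusted p = 8.05e-06, adjusted p = 0.163 with an estimated correlation). Markers of endothelial cells (median -0.22, adjusted p = 0.0001) and of stellate cells (-0.29, adjusted p = 0.00826) were lower in males as lists, with 0 members past the limma threshold and 5 and 3 at an unadjusted p under 0.05. Neither held: adjusted p = 0.163 and adjusted p = 0.55 with an estimated correlation. The stellate call was also lost without female wild-type replicate 1 (markers of stellate cells, adjusted p = 0.0906) and without male wild-type replicate 2 (0.0531). Single members of other lists that were higher in males included Tnf (2.29), the erythroid heme synthesis gene Alas2 (3.07), the asparagine synthetase gene Asns (4.29, endoplasmic reticulum stress) and Oasl1 (1.24, interferon response). The calls for Asns and Oasl1 were kept in 3 and 1 of the 8 fits that left out an array (highest adjusted p = 0.0588 and 0.105).

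All females lay in row 1 of the slide and all males in row 2, so row and sex cannot be told apart in this comparison. The count of 256 depended on the arrays used: it was 130 without female knockout replicate 1, 135 without female knockout replicate 2, 86 without male knockout replicate 1, 92 without male knockout replicate 2, 428 without female wild-type replicate 1, 1057 without female wild-type replicate 2 and 431 without male wild-type replicate 2. Of 33 named genes past the threshold, 23 stayed past it in each of these fits.

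The next comparison asked what loss of Bcl6 does to the male liver. In the arrays labelled male knockout, several genes that mark the female liver rose and several that mark the male liver fell. Cux2 rose at least 109-fold (fitted log2 8.57 ± 0.26 SE, n = 2 per group) and the sulfotransferase Sult2a1 at least 4396-fold. Cyp4a12a fell by 8.18 ± 0.38 on the log2 scale, Elovl3 fell by 10.18 ± 0.48 and Cyp4a12b fell by 8.84 ± 0.66. By limma, 2840 of 26556 passed the threshold, 1532 rising and 1308 falling, and 1443 changed by at least 2-fold. The other large rises were in Sult2a6 (at least 2404-fold), Sult2a2 (at least 1399.6-fold), Cyp3a44 (at least 1336-fold, adjusted p = 0.00024), A1bg (at least 900.4-fold) and Sult3a1 (at least 272-fold). The other large falls were in Nat8f5 (at least 184-fold), Nat8 (52.4-fold) and the cytochrome P450 Cyp2d34 (63.6-fold, adjusted p = 0.000175). Hsd3b5, a steroid dehydrogenase of male liver, fell at least 1581-fold, though its call was lost without any 1 of the 4 male arrays (highest adjusted p = 0.101).

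All 15 of the 24 measured male-biased liver genes that passed the threshold fell (17 adjusted over the list alone, median -2.05, or -1.82 with genes set to their bound), among them Cyp2d9 (-3.75 ± 0.14), C6 (-3.93) and Cyp7b1 (-2.07). Of the female-biased liver genes 25 of 37 rose and 2 fell (31 adjusted over the list alone, median 2.52), with Acot3 up by 4.91 ± 0.18. Camera gave adjusted p = 3.26e-11 and 3.13e-19 for these lists, against adjusted p = 0.215 and adjusted p = 0.133 with an estimated correlation. Among growth hormone and STAT5 signalling genes, 4 of 25 rose and 1 fell (8 adjusted over the list alone). Those that rose include Cux2 and Prlr, already counted among the female-biased liver genes. The receptors for growth hormone, Ghr (2.70), prolactin, Prlr (3.36), and estrogen, Esr1 (2.37), were among those that rose (SE 0.10, 0.19 and 0.22). Prlr stood at 4.51 without male wild-type replicate 1, where another of its probes stood for the gene. With all arrays, a Prlr probe other than the one used gave 4.27. The list passed camera at adjusted p = 0.00876, lost at adjusted p = 0.505 with an estimated correlation and at 0.117 without male wild-type replicate 1.

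In lipid metabolism, members moved both ways in males. PPARA targets and fatty acid oxidation genes had 4 of 43 higher and 5 lower (11 adjusted over the list alone, camera adjusted p = 0.876), with Acot4 up by 2.35. Lipogenesis and triglyceride synthesis genes had 5 of 25 higher and 3 lower (10 adjusted over the list alone, camera adjusted p = 0.851): the desaturases Fads1 (2.07 ± 0.18) and Fads2 (2.09 ± 0.19) and the lipase family member Pnpla5 (3.19) rose, and Mlxipl, a glucose-responsive transcription factor, fell by 1.05. Cholesterol synthesis and uptake genes had 0 of 24 past the limma threshold (4 at an unadjusted p under 0.05, camera adjusted p = 0.456). Of the bile acid synthesis and transport genes 7 of 24 fell, including the transporters Abcc3 (-2.38) and Slco1b2 (-1.22). That list gave 10 adjusted over the list alone, counted in either direction. Its camera adjusted p = 0.0224 was lost at adjusted p = 0.505 with an estimated correlation and without male wild-type replicate 1 or 2. Of the gluconeogenesis and glucose handling genes 4 of 23 fell (6 adjusted over the list alone), led by Pfkfb3 (-3.83 ± 0.47), whose product promotes glycolysis. Camera adjusted p = 0.0155 was lost at adjusted p = 0.351 with an estimated correlation and without male wild-type replicate 1 (0.0645). CAR and PXR targets and drug metabolism genes split, 5 of 30 up and 6 down (16 adjusted over the list alone, camera adjusted p = 0.739): Cyp2b10 rose 22.6-fold, the aldehyde dehydrogenase Aldh1a7 by 2.07 and Nqo1 by 1.41, and Cyp2c54 fell by 1.95.

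Several lists of markers of cells other than hepatocytes were also higher by camera with the preset correlation. Of the markers of B and plasma cells, 5 of 10 rose (5 adjusted over the list alone, median 1.24), among them the antigen receptor chain Cd79b (1.39 ± 0.14) and the plasma cell syndecan Sdc1 (1.48 ± 0.11), and camera gave adjusted p = 0.000219, against adjusted p = 0.215 with an estimated correlation. Extracellular matrix and fibrosis genes had 9 of 20 higher, mostly collagens, with a median of 0.52 (13 adjusted over the list alone, camera adjusted p = 1.26e-07, adjusted p = 0.206 with an estimated correlation). Endothelial markers had 3 of 15 higher, Vwf by 2.63 ± 0.16 (5 adjusted over the list alone, camera adjusted p = 0.000219, adjusted p = 0.215 with an estimated correlation). Stellate cell markers had 2 of 12 higher, markers of macrophages and Kupffer cells 1 of 18 and markers of T and NK cells 1 of 14 (3, 1 and 0 adjusted over the list alone). Their camera adjusted p of 0.0455, 0.0206 and 0.0206 were lost with an estimated correlation, at adjusted p = 0.505, adjusted p = 0.52 and adjusted p = 0.505. The stellate call (markers of stellate cells) was also lost without male wild-type replicate 1 (0.0645) or 2 (0.111) or male knockout replicate 2 (0.268), with normexp (0.0836) and with the mean of a gene's probes (0.0693). The call for markers of macrophages and Kupffer cells was lost without male wild-type replicate 1 (0.0777) or male knockout replicate 1 (0.334), and that for markers of T and NK cells without male knockout replicate 1 (0.0941) or male wild-type replicate 2 (0.0981) or with normexp (0.0649). Acute phase and inflammation genes had 5 of 31 higher and 2 lower, with Itih4 at 1.24 and Tnf at -2.28 (14 adjusted over the list alone). The list median was 0.23 and camera adjusted p = 0.0429, lost at adjusted p = 0.699 with an estimated correlation and, for acute phase and inflammation genes, without male wild-type replicate 1 (0.0777) or male knockout replicate 1 (0.228), with normexp (0.0838), with quantile normalization (0.0509) and with the replicate number as a block (0.0577).

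The remaining lists did not pass camera in males. A single member passed the limma threshold in each of 7 of them. Of markers of hepatocytes 1 of 20 fell, of endoplasmic reticulum stress genes 1 of 22 and of markers of adipocytes 1 of 9 (Adrb3, -5.10). Of markers of erythroid cells 1 of 9 fell (Alas2, -1.49), though the median of these markers was above 0, at 0.49. Of cell cycle genes 1 of 21 rose, of markers of cholangiocytes 1 of 9 (Prom1, at least 4.92-fold) and of genes repressed by Bcl6 in lymphocytes 1 of 18. Of the circadian clock genes 2 of 21 fell, Hlf and Ciart (at least 1.42-fold, fitted -2.57), whose direction turned without female wild-type replicate 1 or male knockout replicate 1 (highest 0.87), and of the markers of pancreatic acinar cells 2 of 8 rose, Pnliprp1 at least 15-fold. By limma, 0 of 23 interferon response genes, 0 of 8 neutrophil markers and 0 of the 5 genes Y-linked or Xist changed (3, 0 and 0 at an unadjusted p under 0.05). Camera adjusted p for these 12 lists lay between 0.0914 and 0.891. The male count of 2840 became 1827 and 1877 without female knockout replicate 1 or 2, 1176 and 1077 without male knockout replicate 1 or 2, and 1410 without male wild-type replicate 2. Of the 72 named genes past the threshold in males, 42 stayed past it whichever array was left out.

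The same question was asked of females. In the arrays labelled female knockout, large rises were in genes not well above background in wild-type females: Ccdc38 rose at least 160.3-fold (fitted log2 9.34 ± 0.14 SE, n = 2 per group), the adrenergic receptor gene Adra2c at least 112-fold and the cation transporter gene Slc22a2 at least 56.3-fold. Cyp2b13 fell by 4.43 ± 0.33, Mfsd2a, a carrier of lysophosphatidylcholine, by 4.05 ± 0.28, and Adgrf1 at least 21.2-fold. By limma, 1574 of 26556 passed the threshold, 923 rising and 651 falling, and 883 changed by at least 2-fold. Cox8b, a subunit of cytochrome oxidase, rose at least 77.4-fold, Cap2 at least 25.5-fold and Tdrd12 at least 20.5-fold. The retinoic acid hydroxylase Cyp26b1 fell by 3.82, the lipid droplet protein Plin4 by 3.69 and the anion exchanger Slc26a4 at least 4.02-fold (adjusted p = 0.00182, 0.00639 and 0.00124). A1bg rose 114-fold, a call lost without female knockout replicate 1 (adjusted p = 0.0653). Without replicate 1 and without replicate 2 of the wild-type females, A1bg rose 43.7-fold and 300.0-fold, the lower bound for Adgrf1 was 34.5-fold and 13.1-fold and Plin4 was at -4.29 and -3.08. Without replicate 1 and without replicate 2 of the females labelled knockout, the lower bound for Cox8b was 149-fold and 40.0-fold.

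The sex-biased lists did not pass as lists in females. Male-biased liver genes had 2 of 24 higher and 4 lower (8 adjusted over the list alone, median -0.44, camera adjusted p = 0.112). Elovl3 fell by a fitted 3.59 (log2), Cyp2d9 by 1.08 and Cyp2f2 2.46-fold, while Cyp7b1 rose by 0.90. Female-biased liver genes had 6 of 37 higher and 2 lower (11 adjusted over the list alone, median 0.01, camera adjusted p = 0.509): Cyp3a44 rose by 5.26 (38.4-fold, and 22.6-fold and 65.2-fold without wild-type replicate 1 and without wild-type replicate 2) and the oxysterol hydroxylase Cyp39a1 fell by 2.70. Growth hormone and STAT5 signalling genes had 3 of 25 higher (4 adjusted over the list alone, camera adjusted p = 0.0828), Ghr by 3.11 ± 0.10 and Prlr by 2.43 ± 0.19. Prlr and the other riser, Cux2, are also counted among the female-biased liver genes. Among PPARA targets and fatty acid oxidation genes 7 of 43 fell and 1 rose (16 adjusted over the list alone): the thioesterase Acot1 fell by 2.09, the peroxisome division factor Pex11a by 1.52 and the peroxisomal beta-oxidation enzyme Ehhadh by 1.01. The list median was -0.22 and camera adjusted p = 6.08e-05, against adjusted p = 0.558 with an estimated correlation. Lipogenesis and triglyceride synthesis genes had 4 of 25 higher and 6 lower (14 adjusted over the list alone, camera adjusted p = 0.247), with Pnpla5 up by 2.31. CAR and PXR targets and drug metabolism genes fell in 6 of 30 cases and rose in 1 (15 adjusted over the list alone): Cyp2c50 fell by 2.60, Cyp2c54 by 2.25 and Cyp2c37 by 2.11, and Aldh1a7 rose by 2.21. Camera gave this list adjusted p = 0.0003, lost at adjusted p = 0.489 with an estimated correlation.

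Bile acid synthesis and transport genes in females had 4 of 24 lower and 1 higher (8 adjusted over the list alone, camera adjusted p = 0.0129), lost at adjusted p = 0.558 with an estimated correlation and, for bile acid synthesis and transport, without female wild-type replicate 1 (0.3) or female knockout replicate 2 (0.0549). Gluconeogenesis and glucose handling genes had 5 of 23 lower (7 adjusted over the list alone, camera adjusted p = 0.026), lost at adjusted p = 0.489 with an estimated correlation and, for gluconeogenesis and glucose handling, without female wild-type replicate 1 (0.118). Acute phase and inflammation genes had 4 of 31 higher, the cytokine Il1b by 1.46 ± 0.11 (9 adjusted over the list alone, camera adjusted p = 0.0124). This call was lost at adjusted p = 0.558 with an estimated correlation and, for acute phase and inflammation, without female knockout replicate 1 (0.15) or female wild-type replicate 1 (0.122). Of markers of B and plasma cells, 2 of 10 rose (6 adjusted over the list alone, median 0.77, Sdc1 at 1.37 ± 0.11), with camera adjusted p = 0.000583 and adjusted p = 0.489 with an estimated correlation. Extracellular matrix and fibrosis genes had 1 of 20 higher (3 adjusted over the list alone, median 0.20, camera adjusted p = 0.00152, adjusted p = 0.489 with an estimated correlation). The other lists did not pass camera in females (adjusted p from 0.0503 to 0.865 over cell types, clock, cell cycle, stress, interferon, cholesterol, sex chromosome and lymphocyte lists). The lowest was that of markers of erythroid cells (median 0.26, adjusted p = 0.558 with an estimated correlation), a list that passed with the preset correlation in 10 of 17 alternatives. Members of these lists that changed included some single genes: Oasl1 rose by 1.49, Prom1 by 2.96 and Pnliprp1 at least 7.1-fold, and Adrb3 fell by 3.27. By limma, 0 of 24 cholesterol synthesis and uptake genes, 0 of 21 cell cycle genes, 0 of 14 T and NK cell markers, 0 of 8 neutrophil markers and 0 of the 5 genes Y-linked or Xist changed (4, 3, 2, 1 and 0 at an unadjusted p under 0.05). The female count of 1574 became 562 and 854 without female knockout replicate 1 or 2, 681 and 726 without male knockout replicate 1 or 2, and 991 without male wild-type replicate 2. Of the 67 named genes past the threshold in females, 33 stayed past it whichever array was left out.

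**Figure D2:**
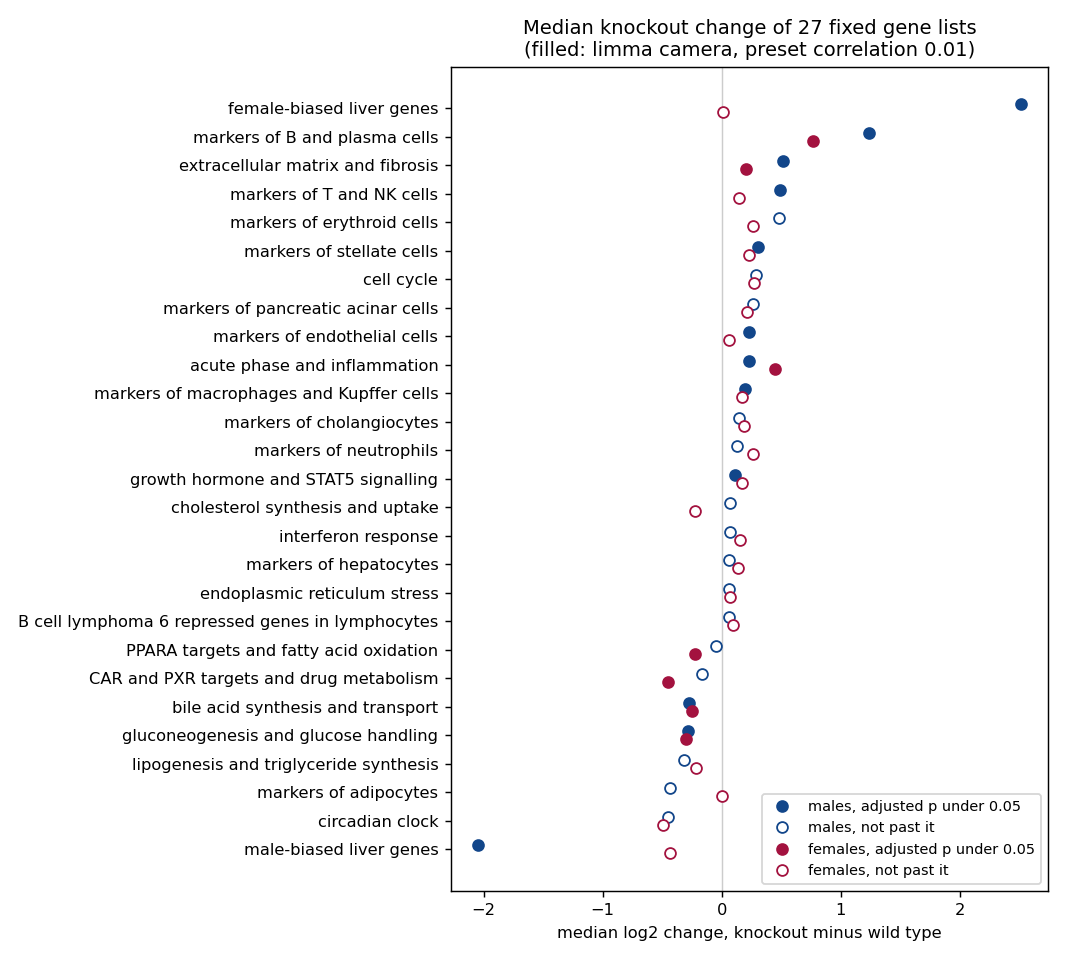
Median log2 change between the arrays labelled knockout and wild type for 27 fixed gene lists, in males and in females; filled points passed camera at an adjusted p under 0.05 with the preset correlation. The female-biased liver genes stand at 2.52 in males and 0.01 in females, and the male-biased ones at -2.05 and -0.44.

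Many genes changed in both sexes. The calls shared 710 rising and 377 falling genes, 1087 together, where independent lists of the same sizes would share 53.2 and 32.1. In opposite directions, 4 genes rose in males and fell in females and 7 did the reverse. Ghr rose by 2.70 and 3.11 in males and females, Pnpla5 by 3.19 and 2.31, and Aldh1a7 by 2.07 and 2.21. Cyp2c54 changed by -1.95 and -2.25, and Adrb3 by -5.10 and -3.27. These comparisons share no arrays, only the estimate of the spread. In both sexes, replicate 2 labelled knockout lay in slide column 3 and replicate 2 of the wild type in column 4. A difference between these columns would enter both comparisons in the same direction. Replicate 1 lay in columns 1 and 2, with the genotypes in opposite order in the 2 sexes. With the slide column as a block, no count moved by more than 1.5 times. Columns 3 and 4 each held 1 genotype, so this block cannot tell a difference between them from one between genotypes. The shared count was 378 and 458 without female knockout replicate 1 or 2, 427 and 439 without male knockout replicate 1 or 2, and 675 and 552 without male wild-type replicate 1 or 2.

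Of the genes that differed between wild-type sexes, most moved toward the female level in the males labelled knockout. Of 160 genes higher in wild-type males 116 fell, Cyp4a12a, Elovl3 and Cyp7b1 among them, and of 96 higher in wild-type females 75 rose, Cux2 and Acot3 among them, 191 in all. Another 8 moved away from the female level. In females, 48 moved toward the male level and 33 away from it. These counts take the direction of a change and not where it ended. In the males labelled knockout, Elovl3, Cux2 and Acot3 went past the wild-type female level. Cux2 rose by a fitted 8.57 against a wild-type difference of 6.95. Cyp4a12a and Cyp7b1 stopped short of that level, Cyp7b1 with a fall of 2.07 against 3.70. Independent lists would give 7.88 and 5.54 for the male counts. In females, 33 male-higher genes rose and 15 female-higher genes fell, where independent lists would share 5.56 and 2.35. Away from the male level, 15 male-higher genes fell and 18 female-higher genes rose, against 3.92 and 3.34. With unchanged knockout arrays simulated against the same wild-type arrays (100 draws), the mean was 0.06 genes toward the female level in males (highest 1) and 0.02 toward the male level in females (highest 1). These simulated knockout comparisons called only 0.08 and 0.03 genes per draw, against 2840 and 1574 in the data, so an overlap near none followed from the setting. The simulated comparison between wild-type sexes called 2751 and 2750, against 256 in the data. The simulation thus gives chance with no effect and does not measure how much of the 191 comes from the shared controls. Splitting a wild-type group leaves 1 array per part, so the calls between wild-type sexes were not made again on split controls. Part of the excess may come from the shared controls. Genes picked by fold in replicate 1 of the wild types were counted in a male comparison without those arrays, given under processing below. When the genes were picked at 2-fold or more in 1 wild-type replicate and measured against the other, the median change of male-higher genes toward the female level in males was 0.63 and 0.57 with replicate 1 or 2 used to pick, against -0.12 and 0.06 toward the male level in females. For female-higher genes it was 0.44 and 0.16 in males against -0.10 and 0.06 in females. The count of 191 became 99 and 105 without female knockout replicate 1 or 2, 68 and 69 without male knockout replicate 1 or 2, 383 without female wild-type replicate 2, and 292 and 373 without male wild-type replicate 1 or 2.

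The comparison between the sexes was repeated in the arrays labelled knockout, where few genes apart from those of the sex chromosomes differed. Eif2s3y, Kdm5d, Ddx3y and Uty, on the Y chromosome, were higher in males, Eif2s3y at least 69.3-fold (log2 7.88 ± 0.31 SE, n = 2 per group), and Xist at least 24.3-fold lower. Of the sex-biased lists 0 members passed the limma threshold, against 9 and 16 in wild type; 7 male-biased and 1 female-biased members had an unadjusted p under 0.05. In total 22 passed, 16 higher and 6 lower in males, with 1595 at an unadjusted p under 0.05. Of the 22, 10 had a gene symbol, 6 of these on X or Y, and 12 differed in the same direction in wild type. Outside the sex chromosomes stood C730036E19Rik, also higher in wild-type males, Il1b (-1.36), the integrin gene Itgb8 (at least 1.69-fold higher in males) and the odorant receptor gene Olfr130 (at least 10.8-fold higher). Calls were lost for Il1b in 6 of the 8 fits that left out an array (all but those without female knockout replicate 2 or male knockout replicate 1, highest adjusted p = 0.133), for Itgb8 without female knockout replicate 1 or either male wild-type array (0.0887), for Olfr130 without either female wild-type array or male wild-type replicate 2 (0.0577), for Kdm5d without either male knockout array, where its other probe stood for the gene (0.861), and for Uty in all fits but those without a female knockout array (0.211).

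Male-biased liver genes as a list still stood higher in males, with a median of 0.53 against 2.55 in wild type (camera adjusted p = 1.68e-05, adjusted p = 0.647 with an estimated correlation, 1 member adjusted over the list alone), and the female-biased median was -0.04 against -2.05 (adjusted p = 0.934). Lipogenesis and triglyceride synthesis genes had a median of 0.24 (camera adjusted p = 0.00256, adjusted p = 0.297 with an estimated correlation) and extracellular matrix and fibrosis genes -0.10 (adjusted p = 0.0199, adjusted p = 0.647 with an estimated correlation), each with 0 members past the limma threshold and 5 and 3 at an unadjusted p under 0.05. The call for lipogenesis and triglyceride synthesis was lost without male knockout replicate 2 (0.1), and that for extracellular matrix and fibrosis without female knockout replicate 1 (0.109) or 2 (0.105) or male knockout replicate 2 (0.1). The count of 22 became 101 and 217 without female knockout replicate 1 or 2, 190 and 158 without male knockout replicate 1 or 2, and 11 without either female wild-type array.

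**Figure D3:**
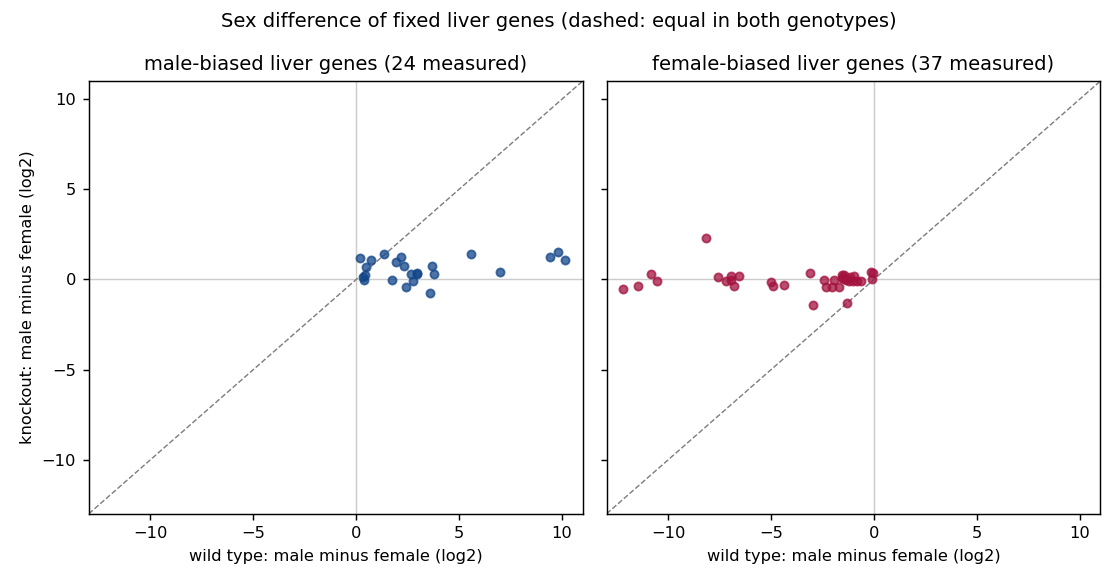
Male minus female log2 difference in wild type (x axis) and in the arrays labelled knockout (y axis) for 24 male-biased and 37 female-biased liver genes; each point is a gene and the dashed line marks equal differences. The male-biased median was 2.55 in wild type and 0.53 in the arrays labelled knockout, and the female-biased one -2.05 and -0.04.

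The interaction tested directly whether the difference between the genotypes differed between the sexes, which is also the test of whether the sex difference changed. For Cyp4a12a the log2 difference between the arrays labelled knockout and wild type was -8.18 in males and 0.01 in females, an interaction of -8.20 ± 0.53 (SE, n = 2 per group, limma adjusted p = 0.0095). The differences in males and females were -5.71 and -0.47 for Nat8 and 8.02 and 0.30 for Slc22a26. These are fitted values, and for Slc22a26 they depend on wild-type male arrays not well above background. Cyp2b13 moved in opposite directions, by 5.99 in males and -4.43 in females, and Cyp7b1 by -2.07 and 0.90. In total 51 passed the threshold, 24 with a more positive and 27 with a more negative difference in males. Female-biased liver genes had 8 of 37 members past it, all with the more positive difference in males (26 adjusted over the list alone, median 1.82, camera adjusted p = 2.33e-38), and this call held at adjusted p = 0.0362 with an estimated correlation. Male-biased liver genes had 7 of 24, all with the more negative difference in males (13 adjusted over the list alone, median -2.49, camera adjusted p = 2.83e-13, adjusted p = 0.277 with an estimated correlation). The count of 51 was 80 and 191 without female knockout replicate 1 or 2, 144 and 531 without female wild-type replicate 1 or 2, 119 and 113 without male knockout replicate 1 or 2, and 138 and 276 without male wild-type replicate 1 or 2. Across all 5 comparisons 39 of 140 list tests passed camera with the preset correlation and 2 with an estimated one. In 21 of the 140 the median, the mean and the test of a list differed in sign, and none of those 21 passed. In males these were PPARA targets and fatty acid oxidation (median -0.04, mean 0.13), lipogenesis and triglyceride synthesis (-0.31, 0.09), endoplasmic reticulum stress (0.06, -0.08) and markers of hepatocytes (0.07, -0.02), and in females markers of adipocytes (0.0028, -0.29). Between wild-type sexes they were growth hormone and STAT5 signalling, acute phase and inflammation, genes repressed by Bcl6 in lymphocytes and markers of erythroid cells. Between the sexes labelled knockout they were gluconeogenesis and glucose handling, circadian clock and markers of T and NK cells, of B and plasma cells and of erythroid cells. For the interaction they were bile acid synthesis and transport, circadian clock, cell cycle, endoplasmic reticulum stress, Y-linked and Xist, and markers of cholangiocytes and of erythroid cells.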

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

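Each test of an explanation named here was chosen only after the result it bears on was seen, except the count of Bcl6 probes. The results listed first are those for which the change between the arrays labelled knockout and wild type differed between males and females by the interaction test.

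Among genes with the more positive difference between genotypes in males, the fitted interaction (log2) was 10.46 for Sult3a1, 10.42 for Cyp2b13, 7.71 for Slc22a26, 6.91 for Cux2, 6.73 for Cyp3a44, 5.26 for Olfr130, 4.09 for Acot3, 2.99 for Itgb8 and 1.71 for Acot4. On the other side it was -9.07 for Cyp4a12b, -8.20 for Cyp4a12a, -6.60 for Elovl3, -6.11 for Nat8f5, -5.24 for Nat8, -4.37 for Cyp2d34, -3.49 for C6, -3.08 for Alas2, -2.97 for Cyp7b1 and -2.67 for Cyp2d9. These are fitted values and not bounds: Sult3a1, Slc22a26, Cux2 and Cyp3a44 were well above background on no wild-type male array, Nat8f5 on no array labelled knockout, and Olfr130 and Itgb8 only in males labelled knockout, so the size of their interaction is uncertain. Adjusted p-values (limma) ran from 0.0095 for Acot3 to 0.0458 for Itgb8. Cyp2b13 came to similar levels from opposite sides, 6.60 ± 0.70 (mean ± SD, n = 2) in wild-type females, -3.92 ± 0.24 in wild-type males, and 2.17 ± 0.05 and 2.07 ± 0.26 in the females and males labelled knockout. Alas2 did so as well, from 2.06 ± 0.33 and 5.13 ± 0.15 to 3.66 ± 0.26 and 3.64 ± 0.19. Cyp2d34, Cyp3a44, Itgb8 and Olfr130 were not among the interactions followed with an array left out, so whether their calls depend on 1 array was not tested. Without replicate 1 and without replicate 2 of the wild-type females, the fitted interaction was 11.57 and 9.35 for Sult3a1. It was 8.31 and 7.12 for Slc22a26 and -7.99 and -10.16 for Cyp4a12b. Calls were lost with an array left out for Sult3a1 (female knockout replicate 1, male wild-type replicate 1 or male knockout replicate 2, highest adjusted p = 0.0774), Elovl3 (female or male wild-type replicate 1 or male knockout replicate 1, 0.0734), C6 (female knockout replicate 1 or either male knockout array, 0.0753), Alas2 (female knockout replicate 1, male wild-type replicate 1 or either male knockout array, 0.0774), and Cyp4a12b and Acot4 (any array but a female wild-type one, 0.0975 and 0.102).

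Lists with an interaction by camera were the male-biased liver genes (median -2.49, adjusted p = 0.277 with an estimated correlation), female-biased liver genes (1.82, 0.0362), PPARA targets and fatty acid oxidation (0.19, 0.502), lipogenesis and triglyceride synthesis (0.15, 0.277), cholesterol synthesis and uptake (0.25, 0.833), CAR and PXR targets and drug metabolism (0.32, 0.277), extracellular matrix and fibrosis (0.26, 0.278) and markers of endothelial cells (0.17, 0.277). With the preset correlation the adjusted p was lost for lipogenesis and triglyceride synthesis without female knockout replicate 2 (0.0653), female wild-type replicate 2 (0.205), male wild-type replicate 1 (0.0625) or male knockout replicate 2 (0.167). For cholesterol synthesis and uptake it was lost without female knockout replicate 1 (0.384), female wild-type replicate 1 (0.0534) or 2 (0.325), male wild-type replicate 1 (0.604) or male knockout replicate 2 (0.541) or with the deposited value table (0.0593), and for extracellular matrix and fibrosis without female wild-type replicate 2 (0.0897).

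The first pattern weighed was the smaller sex difference in the arrays labelled knockout. A larger spread between knockout arrays was argued against, since the larger of the knockout groups' median replicate differences was 0.155 (log2) and the smaller wild-type one 0.167. A wrong sex label on a knockout array was argued against by the gap of 4.37 over Xist and 4 Y-linked genes. By the design each row of the slide held 1 sex and both genotypes, so a row that adds the same difference in both genotypes cancels in the interaction; a row acting differently on the genotypes was not tested. What stays open is a change mainly on the male side: in genes picked in 1 wild-type replicate and measured against the other, the median change toward the other sex was larger in males in all 4 cases, by 0.10 or more, which is in line with males moving more than females, a hypothesis from the same arrays it was seen in.

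The second pattern was that the Bcl6 probe was not lower in the arrays labelled knockout. An exchange of all genotype labels was argued against on the background that wild-type livers carry the sex difference: the male-biased list differed between the sexes by 2.02 more (log2) in the arrays labelled wild type. A single array with the wrong genotype label was argued against too, since each of the 8 correlated better with its own replicate than with the other genotype of its sex, by at least 0.0117. A probe outside the deleted part stays open: there was 1 Bcl6 probe, and its position relative to the deletion is not given in the sources used here. Bcl6 is also expressed in cells other than hepatocytes, which was not tested.

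The third pattern was the higher list of B and plasma cell markers in the males labelled knockout (5 of 10 members past the threshold; the list call was lost at adjusted p = 0.215 with an estimated correlation). A lower share of hepatocytes, which would raise the markers of all other cell types alike, stays open: the mean change was 0.96 over the 10 markers and 0.32 over 102 markers of 9 other types (permutation test, two-sided p = 0.0779; in females 0.73 and 0.26, p = 0.0881), against 0.36 over 76 markers of 6 types when erythroid, pancreatic acinar and adipocyte markers were left out (p = 0.0138; in females 0.22, p = 0.00852). The permutation test exchanged marker genes, which are not independent replicates. Its p-values measure the spread across genes and not between samples. More B cells in the liver stays open as well. Of the 10 markers 8 were above 0 in both sexes, but Mzb1 (-0.43) and Pax5 (-0.052) were below 0 in males. Cd79b went from -1.30 ± 0.22 to 0.09 ± 0.11 and Sdc1, which hepatocytes also express, from 3.33 ± 0.11 to 4.81 ± 0.11 (log2, mean ± SD, n = 2). The tissue was whole liver, so no sort would have removed such cells.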

How the results depend on the processing

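All alternatives named here were planned. Of 197 named gene results, 94 kept their direction and their side of the threshold under every alternative run; of 3466 pairs of a result and an alternative, 536 lost the call in the same direction and 3 reversed. Quantile normalization, the slide column as a block and the mean of a gene's probes moved no count by more than 1.5 times, and neither did the deposited value table. Without the filter on dim probes the counts fell to 1225 from 2840 in males, 522 from 1574 in females, 99 from 256 between wild-type sexes, 16 from 51 for the interaction, 80 from 191 toward the female level and 386 from 1087 in both sexes, with more genes tested; the cause was not tested. With normexp on the medians they were 2652 in females, 615 between wild-type sexes, 10 from 22 between the sexes labelled knockout, 392 toward the female level and 1647 in both sexes; the cause was not tested. A mean-variance trend with a robust prior gave 2531 in females, 592 between wild-type sexes and 392 toward the female level; the cause was not tested. A fit of only the 2 groups compared, with fewer samples, gave 362 in females, 42 between wild-type sexes, 11 between the sexes labelled knockout, 31 toward the female level and 268 in both sexes. The filter on all 8 arrays, which removes genes absent from 1 group, left 1 gene between the sexes labelled knockout. At 2-fold or more, 1443 passed in males and 883 in females, and at a threshold of 0.10 4591, 3245, 887 between wild-type sexes and 90 for the interaction. Genes picked at 2-fold or more in replicate 1 of the wild types gave 378 toward the female level. These were 223 of 907 picked as higher and 155 of 704 picked as lower in wild-type males, with 58 and 12 away from it. The pick was by fold and not by the threshold, so 378 is not comparable with 191. With an estimated correlation 2 list calls of 39 were left.

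Replicate numbers did not pair the samples: over pairs of groups, the replicate differences correlated between -0.0018 and 0.102 across genes, and the labels give no shared litter, batch or day. With the replicate number as a replicate block, the interaction count was 25 and the count toward the female level 127; the others were 2465 in males, 1252 in females, 171 and 17 between the sexes and 867 in both, and 42 list calls.

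Leaving out 1 array leaves an arm with 1 sample, assumed to vary like the others. The counts then ranged from 1077 to 2911 in males, 562 to 1692 in females, 86 to 1057 between wild-type sexes, 11 to 217 between the sexes labelled knockout, 80 to 531 for the interaction, 68 to 383 toward the female level, 378 to 962 in both sexes and 36 to 45 list calls. The interaction median ranged from -2.63 to -1.42 for the male-biased and 1.48 to 2.40 for the female-biased list. Bcl6 ranged from 0.27 to 1.34 in males and -0.29 to 2.50 in females, reversed to -0.29 without female knockout replicate 2, where its arrays differ most. Ciart in males (-2.57) ranged from -3.21 to 0.87 and reversed to 0.52 without the filter, 0.52 without female wild-type replicate 1 and 0.87 without male knockout replicate 1, where the other of its 2 probes stood for the gene.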

Other observations

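The rule behind the counts of genes read in one genotype only was chosen after the data were seen; the tests on DNA next to Bcl6 were written before their results.

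Beyond the sex-biased genes, a set of genes not well above background in wild-type liver was well above it in the arrays labelled knockout of both sexes. By limma, 82 genes (44 with a symbol) rose in both sexes and were well above background on all 4 arrays labelled knockout and on none of the 4 wild-type arrays. Their lower bounds ran from 1.24-fold to 151-fold in males and from 1.6-fold to 160.3-fold in females. Some of them thus lay little above the lowest signal called well above background. The converse held for 5 (2 with a symbol, Nat8f5 and Slc26a4). Examples, picked from these after their values were seen and not tested for a tissue of origin, were the following: Adra2c, an adrenergic receptor of neurons, rose at least 131-fold in males and 112-fold in females, Slc22a2, a cation transporter of kidney, at least 79.9-fold and 56.3-fold, and Cox8b, a cytochrome oxidase subunit of muscle and brown fat, at least 31.1-fold and 77.4-fold (in females 149-fold and 40.0-fold without female knockout replicate 1 and without replicate 2). Col22a1, a collagen of tissue junctions, rose at least 48.1-fold and 39.8-fold, the ceramidase Acer1 at least 27.5-fold and 22-fold, and Cga, the alpha subunit of pituitary glycoprotein hormones, at least 15.6-fold and 15.4-fold. Tdrd12 and Tdrd9, tudor proteins of germ cells, rose at least 24.4-fold and 7.62-fold in males and at least 20.5-fold and 6.7-fold in females.

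Some members of the cell type lists changed in both sexes. Among markers of pancreatic acinar cells, Pnliprp1 rose at least 15-fold in males and at least 7.1-fold in females, with 2 of 8 members changed in each sex. Prom1, a marker of cholangiocytes, rose at least 4.92-fold in males and by 2.96 ± 0.29 (log2, SE, n = 2 per group) in females, and Vwf, an endothelial marker, rose by 2.63 and 1.15; the female call for Vwf was lost without female knockout replicate 1 or female wild-type replicate 2 (highest adjusted p = 0.0954). Adrb3, an adrenergic receptor of fat cells, changed by -5.10 and -3.27.

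The 2 wild-type females differed from each other in several sulfotransferase genes, whose probes may bind other members of the family. No list was tested between them. Sult2a1 stood at 8.04 and 2.61 (log2) in replicates 1 and 2, and Sult2a2 at 7.43 and 4.05, against 8.08 and 8.35 and 6.93 and 6.59 in the females labelled knockout. For Sult2a6 the bound of the wild-type male minus female difference was -12.55 without female replicate 2 and -7.94 without replicate 1. For Sult3a1, higher in replicate 2, it was -5.01 and -7.23. The median replicate difference over all genes was 0.207 in wild-type females, 0.155 in females labelled knockout, 0.167 in wild-type males and 0.126 in males labelled knockout.

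A hypothesis tested here was that DNA next to Bcl6, carried along from the cells in which the gene was targeted, accounts for genes changed in the same direction in both sexes. Of the 20 nearest named and measured genes on each side of Bcl6, 1 of 40 changed in both sexes (2.5%, Il1rap, at -2.42 in males and -1.76 in females), against 732 of the 15484 other genes with a symbol (4.73%; Fisher's exact two-sided test, p = 1). For single neighbours the explanation could not be settled with so few genes. As a direct effect on genes of the same chromosome, it was argued against for the whole pattern. Of the 733 genes with a symbol changed in both sexes, 22 (3.0%) lay on the chromosome of Bcl6, which holds 3.11% of all genes measured. An effect of changed neighbours on genes of other chromosomes would not show in this share and was not tested.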
